A study of Mus musculus with 23 samples.

How the data were processed

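Hematopoietic stem cells (HSC) and lymphoid-primed multipotent progenitors (LMPP) had been sorted from bone marrow of pooled transplant recipients, per the labels' design text. HSC were lineage-negative, c-Kit-positive, Flk2-negative, CD150-positive and CD48-negative cells, and LMPP carried the opposite Flk2, CD150 and CD48 phenotype. The marrow was wild type (WT), lacked p110α (here alphaKO), lacked p110δ (deltaKO) or lacked both (DKO). p110α and p110δ are catalytic subunits of class I phosphoinositide 3-kinase (PI3K), encoded by Pik3ca and Pik3cd. Each of the 23 samples was 1 Affymetrix Mouse Transcriptome Assay 1.0 array hybridised with biotin-labelled RNA. All groups held 3 arrays except LMPP WT, which held 2. Per the labels each group of 3 had 1 female and 2 male samples, and LMPP WT had 1 of each. The labels do not say whether arrays of a group came from separate pools of recipients, so p-values measure the spread between these samples, which may be technical. They also do not say whether HSC and LMPP of a genotype came from the same pools, and fits of both cell types treat all arrays as independent. The number of arrays limits the precision.

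The deposited value table holds log2 RMA expression values per transcript cluster, made by the authors with Expression Console, per the labels. The tools named in the submitters' processing notes were Affymetrix Expression Console and Transcriptome Analysis Console, whose versions are not given in the sources used here. The genome build and annotation release are also not given in the sources used here. The authors deposited 6 comparison tables, 1 for each knockout against WT in each cell type, and 2 tables of overlapping genes, which were not used. Per the file headers these hold biweight average signals on the log2 scale, a signed linear fold change, and an unadjusted p-value and an FDR p-value. Every deposited entry had a fold of at least 2.01 in either direction and an unadjusted p-value of at most 0.05, as read from the values.

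Of the 72688 rows of the value table, 6732 were array controls and were left out. Transcript clusters were tested when their mean over the 23 arrays was at or above the median of such means, log2 4.95, which left 32978. Each cell type was fitted on its own with limma 3.58.1 (lmFit and eBayes, without trend or robust options) in R 4.3.3, with 1 mean per genotype, so that the groups of a cell type shared 1 estimate of spread. Adjusted p-values are Benjamini-Hochberg values over the clusters tested, and a call is an adjusted p below 0.05. The interaction contrast was DKO minus alphaKO minus deltaKO plus WT. HSC and LMPP were compared in a fit of all 8 groups, averaged over genotypes, and the difference between cell types in the effect of a knockout was tested there by limma's F test over the 3 knockouts. DKO was also compared with alphaKO and with deltaKO in the same fits, a comparison chosen after seeing the data. Figures were drawn and the deposited averages rebuilt with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

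Gene names came only from the authors' comparison tables, which list 1617 clusters, of which 561 carry a symbol and 524 carry exactly 1. After predicted genes, small RNAs and receptor families were set aside, 306 could be named and 280 of these were tested. The authors selected all of these clusters on the same arrays because they differed from WT, so a named gene or a list of such genes is not independent evidence of its direction. Symbols were compared with the reference gene table, whose coordinates were used only for the order of genes along chromosome 4. Of 442 clusters with a symbol in that table, 441 had the same chromosome in the cluster's identifier. Pik3ca, Pik3cd, Pik3cb, Pik3cg and Pik3r1, and the sort markers encoded by Flt3, Slamf1, Cd48 and Kit, were not analysed here, so the knockouts were not checked at the level of the targeted gene.

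The groups, the main tests, the naming rule, the 25 gene lists and most alternatives were fixed before the data were examined. By the naming rule each knockout comparison names up to 10 genes per direction with the largest log2 fold change among the calls whose groups did not overlap. Where fewer passed, the places were filled by smallest unadjusted p from genes of at least 1.5-fold whose groups did not overlap. With 3 arrays against 3, chance gives such a separation in 1 direction or the other for 10% of genes. Against the 2 arrays of LMPP WT chance gives it more often. The rule also names up to 4 members of a list past the threshold adjusted over the list alone, the 2 members with the smallest p-value of a list called without such a member, and the 5 genes with the largest deposited fold in each direction. The text gives examples from these names.

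List shifts were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives, over 6 comparisons. The 8 lists with at least 3 named and tested members were FOXO targets (8 members), HSC identity (3), myeloid (9), G2 and M phase (4), quiescence and immediate early (3), inflammatory NF-kB (4), p53 targets (4), and adhesion and homing (3). Further lists with 1 or 2 such members are given by gene: PI3K components, S phase, interferon response, ribosome biogenesis and MYC, autophagy and lysosome, macrophages and dendritic cells, mast cells and basophils, and handling stress. No named member was tested for 8 lists, which were lymphoid priming, megakaryocyte and erythroid, glycolysis and hypoxia, oxidative phosphorylation, B cells, T and NK cells, stroma and endothelium, and sex-linked genes. Groups of granulocyte, immunoglobulin and immediate early genes were written down after the data were seen.

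The fits were tested on simulated arrays with 200 clusters changed by known amounts among 32978. For HSC deltaKO against WT, 50.7% of changes of log2 1, 91.0% of changes of log2 2 and 95.5% of changes of log2 4 were recovered, with 13 false calls. For LMPP deltaKO against WT the shares were 22.4%, 71.6% and 90.9%, with 8 false calls. These simulated values were independent normal draws with 1 spread per cluster, so no array stood apart and no clusters shared values. The counts of false calls are therefore no error rate of the fits of the real arrays. The alternatives were other filters, quantile normalization, centring each array on its median, other eBayes settings, sex as a covariate, array weights, other sets of arrays in the fit, an unadjusted criterion, and leaving out each array. Overlap between knockouts was set beside 20 simulations of unchanged groups.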

Results

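RNA of HSC and LMPP from WT, alphaKO, deltaKO and DKO marrow was profiled on 23 arrays. Array medians ranged from log2 4.83 to 5.04 for 22 of the arrays and the median of LMPP WT replicate 2 was 5.29. That array also had the lowest mean correlation with the other arrays of its cell type, at 0.949 against 0.970 to 0.985 for the rest. Its values had an SD of 2.47 over all clusters, against 2.68 to 2.77 for the other arrays. As LMPP WT held only 2 arrays, each LMPP comparison with WT rests partly on it. The plot of the first 2 principal components shows this array apart from the others along component 2. Among the HSC arrays HSC WT replicate 3 had the lowest mean correlation, at 0.973 against 0.980 to 0.985 for the others. It also had the lowest value on component 3, -83.9, with -36.2 for the next array. Each HSC comparison with WT rests partly on HSC WT replicate 3. Transcripts of the Y chromosome were higher in every male than in every female array for 5 clusters, which matched the labelled sex of all samples.

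**Figure D1:**
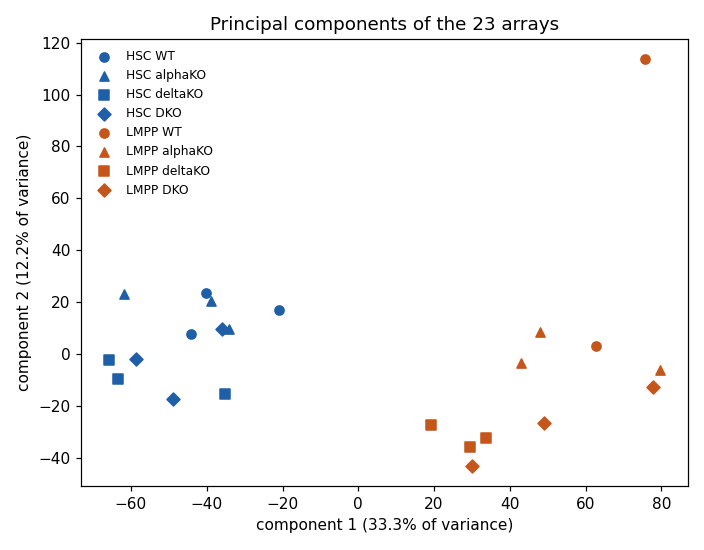
Principal components of the RMA values (log2) of the 23 arrays, with 1 point per array, cell type by colour and genotype by marker. Component 1, with 33.3% of the variance, separates HSC from LMPP, and LMPP WT replicate 2 lies at 113.6 on component 2.

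The comparison of cell types asked which genes separated the sorted populations. The endothelial and stem cell genes Vwf (von Willebrand factor) and Tek (the angiopoietin receptor Tie2) were higher in HSC. Vwf measured log2 9.38 ± 0.62 (SD, n = 12) in HSC and 5.54 ± 0.16 (SD, n = 11) in LMPP. Granulocyte and monocyte genes were higher in LMPP. Ly6c2, which encodes a Ly6C antigen of myeloid cells, was at 8.47 ± 2.01 in HSC and 15.78 ± 1.44 in LMPP, and the granule protease gene Ctsg was at 6.86 ± 0.93 and 13.03 ± 1.07. Adjusted p by limma was 4.01e-12 for Vwf, 1.13e-11 for Tek, 1.37e-07 for Ly6c2 and 8.83e-10 for Ctsg.

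Over all clusters 7694 differed, 4226 higher in HSC and 3468 higher in LMPP. Of the 280 named and tested genes, 59 were higher and 132 lower in HSC. All 9 myeloid genes were lower in HSC, and Ms4a3, a gene of granulocyte and monocyte progenitors, differed by -6.83. All 4 mitotic genes (Bub1, Cenpe, Kif11 and Top2a) were lower in HSC, with Kif11 at -1.40 (SE 0.21). All 3 HSC identity genes (Vwf, Tek and Selp) were higher in HSC. Of the 4 NF-kB genes all were lower in HSC, from -3.04 for the interleukin-1 receptor gene Il1r1 to -0.73 for Ptgs2. Among FOXO targets Irs2 was higher in HSC by 1.39 (SE 0.30) and Bcl6 lower, at -0.97 (SE 0.10). In the quiescence and immediate early list Klf4 and Nr4a1 were higher in HSC, by 1.02 and 1.01, and Cdkn1a differed by -0.23 with an adjusted p of 0.701. The p53 target Pmaip1 was lower in HSC at -1.62, and the adhesion receptor gene Cd44 was lower at -1.42.

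Of the shorter lists, the PI3K pathway gene Rictor was higher in HSC by 0.67 (SE 0.13), as were the interferon-induced genes Ddx58, by 0.68, and Ifit2, by 0.48. The S phase gene Cdc6 was lower in HSC at -0.56, as were the macrophage genes Vcam1, at -2.00, and Slc40a1, at -0.82, and the mast cell genes Hdc, at -3.11, and Cpa3, at -1.61. Srm of the ribosome biogenesis list differed by 0.04, Sqstm1 of the autophagy list by -0.03, and the handling stress genes Ddit3 and Gadd45b by -0.04 and -0.21, none of them past the threshold. With WT arrays alone the count of differing clusters was 2789.

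Loss of p110α in HSC was examined for its effect on these cells. The mitotic genes Kif11 and Bub1 and the myeloid gene Ms4a3 had means below WT. Kif11, a mitotic kinesin, measured log2 11.01 ± 0.82 (SD, n = 3) in alphaKO and 12.14 ± 0.15 (SD, n = 3) in WT, and Bub1, a spindle checkpoint kinase gene, measured 8.32 ± 0.56 and 9.41 ± 0.09. Ms4a3 was at 5.41 ± 0.24 in alphaKO and 7.34 ± 1.04 in WT. Clec7a, which encodes the receptor dectin-1, had a log2 difference from WT of 1.05 (SE 0.38). None of these passed the threshold for single genes, with limma adjusted p of 1.000 for each.

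Limma made 0 calls in HSC alphaKO against WT, with 919 clusters at an unadjusted p below 0.05. All 4 G2 and M phase genes had negative values, with a mean of -0.98 and a camera adjusted p of 2.03e-05, and the list's adjusted p was 0.311 with an estimated correlation. Of these members 0 passed over all clusters and 1, Bub1, passed adjusted over the list alone, and without HSC alphaKO replicate 1, the lowest array for both, Kif11 was at -0.65 and Bub1 at -0.80. As all members of these lists were picked by the authors on these arrays, neither list is independent evidence of its direction. All 9 myeloid genes had negative values, with a mean of -1.54 and a camera adjusted p of 0.000103, against an adjusted p of 0.510 with an estimated correlation. The authors' deposited table for this comparison listed 36 clusters, with Ly6c2 at a fold of -9.21, and its smallest FDR p-value was 0.956.

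In HSC without p110δ the immediate early genes Nr4a1 and Klf4 and the inflammatory gene Ptgs2 had means below WT. Nr4a1, an orphan nuclear receptor gene induced rapidly by many stimuli, measured log2 15.92 ± 0.49 (SD, n = 3) in deltaKO and 17.32 ± 0.58 (SD, n = 3) in WT. Klf4, a transcription factor gene, was at 12.62 ± 0.08 against 14.23 ± 0.77, and Ptgs2, which encodes cyclooxygenase-2, was at 8.34 ± 0.15 against 9.61 ± 0.31. Vwf was at 9.85 ± 0.53 in deltaKO and 8.80 ± 0.40 in WT. None of the 4 passed the threshold, with limma adjusted p of 0.384 for Nr4a1, 0.457 for Klf4, 0.187 for Ptgs2 and 0.489 for Vwf.

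The 3 calls were all unnamed clusters that rose in deltaKO, with 2760 clusters at an unadjusted p below 0.05. The largest was cluster TC0400001906.mm.1 on chromosome 4, at 9.45 ± 0.71 in deltaKO and 5.25 ± 0.45 in WT (adjusted p 0.0137). All 3 members of the quiescence and immediate early list (Cdkn1a, Klf4 and Nr4a1) had negative values, with a mean of -1.61 and a camera adjusted p of 0.000503, against an adjusted p of 0.276 with an estimated correlation. Of them 0 passed over all clusters and 3 adjusted over the list alone, and, picked by the authors on these arrays, they are not independent evidence. Of the 4 NF-kB genes 3 passed adjusted over the list alone and 0 over all clusters, namely Ptgs2, the NF-kB inhibitor gene Tnfaip3 at -1.18, and Il1r1 at 0.68, and the list's camera adjusted p was 0.0684. The handling stress genes Ddit3 and Gadd45b had values of -1.13 and -1.15 in the same comparison, and of -0.59 and -0.60 without HSC WT replicate 2. The authors' deposited table listed 339 clusters, 305 higher and 34 lower, with a smallest FDR p-value of 0.534. The 3 calls became 0 with sex as a covariate, with only the 2 groups in the fit, and without HSC deltaKO replicate 1 or HSC WT replicate 3, and 1 without HSC deltaKO replicate 2.

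In HSC without both isoforms Nr4a1 and Klf4 had means below WT and Ncam2, Pim2 and Pde2a means above it. Nr4a1 measured log2 15.78 ± 0.52 (SD, n = 3) in DKO, a difference from WT of -1.54, and Klf4 measured 12.38 ± 0.86, a difference of -1.85. Ncam2, a neural cell adhesion molecule gene, was at 9.32 ± 0.09 in DKO and 6.30 ± 0.18 in WT. The serine/threonine kinase gene Pim2 was at 10.17 ± 0.36 against 8.64 ± 0.50, and Pde2a, a cyclic nucleotide phosphodiesterase gene, was at 9.62 ± 0.52 against 7.88 ± 0.26. Limma adjusted p was 0.306 for Nr4a1, 0.376 for Klf4 and 0.193 for each of Ncam2, Pim2 and Pde2a, so none passed.

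The calls were 1 cluster that rose and 2 that fell, with 2784 at an unadjusted p below 0.05. Cluster TC0400001906.mm.1 rose by 4.18 (SE 0.38), and the predicted genes LOC100861716 and Gm5945, named here after their values were seen, fell by 1.37 and 2.24 on the log2 scale. The quiescence and immediate early genes had a mean of -1.76 in 3 of 3 members (camera adjusted p 6.96e-05, and adjusted p 0.178 with an estimated correlation), with 3 past the threshold adjusted over the list alone and 0 over all clusters. The 4 mitotic genes had a mean of -0.92 (camera adjusted p 0.000576, and adjusted p 0.256 with an estimated correlation). The 3 HSC identity genes had positive values, with a mean of 0.57 (camera adjusted p 0.0351, and adjusted p 0.256 with an estimated correlation). Camera also called FOXO targets, which had a mean of -0.37, p53 targets, with a mean of -0.85, and myeloid genes, with a mean of -1.01, and their adjusted p was 0.381, 0.322 and 0.423 with an estimated correlation. Cdkn1a, at -1.88 and with an SD of 1.47 in HSC WT, is a member of the FOXO, p53 and quiescence lists, so these 3 calls are not separate. The FOXO targets had a median of -0.19, with 3 of 8 positive. The myeloid genes differed between DKO arrays, with Camp at 13.52 in HSC DKO replicate 2, above every WT array, and at 7.27 and 7.08 in replicates 1 and 3. The members of all 6 lists were picked by the authors on these arrays and are not independent evidence of a direction. With only named genes as the background the camera adjusted p was 0.0178 for quiescence and immediate early genes. It was then 0.0562 for both mitotic and HSC identity genes, 0.501 for FOXO targets, 0.317 for p53 targets and 0.509 for myeloid genes. The handling stress genes Ddit3 and Gadd45b had values of -1.17 and -1.01, and the mast cell gene Cpa3 one of -1.41. In HSC WT arrays Ddit3 ranged from 10.11 to 11.80 and Gadd45b from 10.66 to 12.51. As in deltaKO, the values of both against these WT arrays are smaller without HSC WT replicate 2. The authors' deposited table listed 251 clusters, with Ncam2 highest among the named genes at a fold of 8.1. Without HSC WT replicate 3 or HSC DKO replicate 3 the 3 calls became 0, with 1 call without HSC WT replicate 1, HSC WT replicate 2 or HSC DKO replicate 2, 5 without HSC DKO replicate 1 and 1 with only the 2 groups in the fit.

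**Figure D2:**
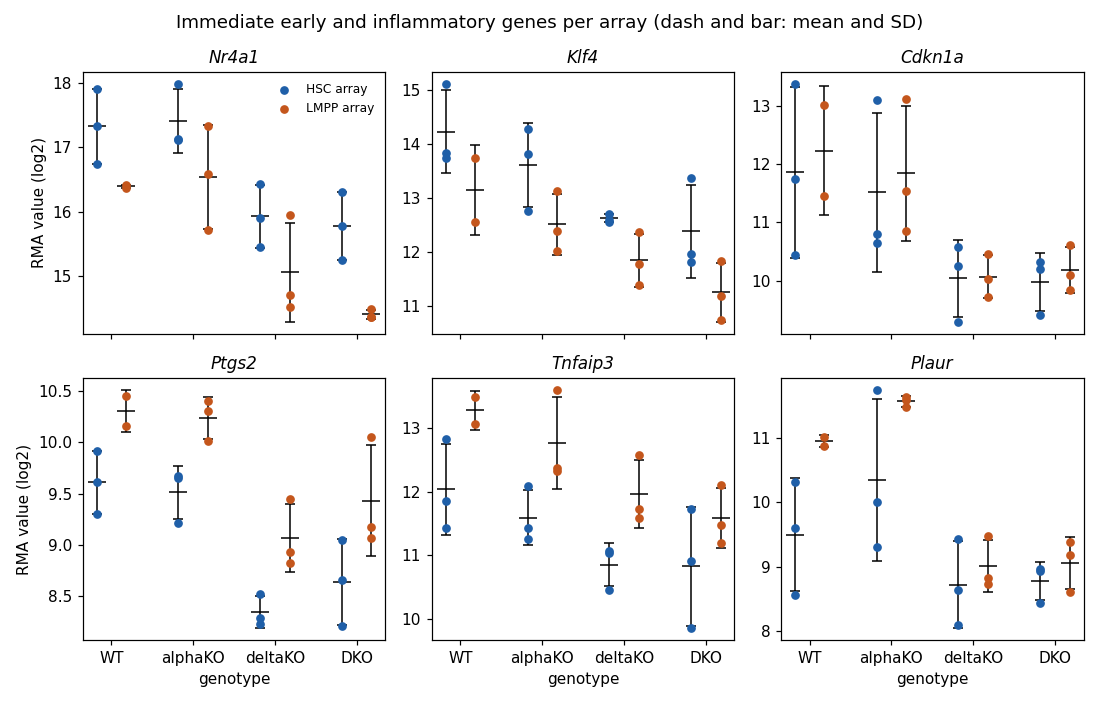
RMA values (log2) of 6 immediate early and inflammatory genes by genotype, with 1 point per array, HSC in blue and LMPP in orange, and dash and bar for the mean and SD of a group (2 arrays in LMPP WT and 3 in the others). Nr4a1 in HSC averaged 17.32 in WT, 17.40 in alphaKO, 15.92 in deltaKO and 15.78 in DKO.

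In LMPP without p110α the FOXO targets Irs2, Sesn1 and Insr had means above WT and the immunoglobulin gene Ighv1-62-1 a mean below it, none past the threshold over all clusters. Irs2, an insulin receptor substrate gene, measured log2 11.82 ± 0.68 (SD, n = 3) in alphaKO and 10.30 ± 0.17 (SD, n = 2) in WT. The stress response gene Sesn1 was at 9.92 ± 0.36 against 8.79 ± 0.73, and the insulin receptor gene Insr was at 9.20 ± 0.07 against 8.25 ± 0.47. The immunoglobulin heavy chain gene Ighv1-62-1 was at 6.81 ± 0.36 in alphaKO and 9.69 ± 0.94 in WT. Limma adjusted p was 0.553 for Irs2, Sesn1 and Insr and 0.196 for Ighv1-62-1.

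Limma made 0 calls in this comparison, with 2880 clusters at an unadjusted p below 0.05. Of 8 FOXO targets 5 had positive values, with a mean of 0.44, and 3 (Irs2, Sesn1 and Insr) passed adjusted over the list alone and 0 over all clusters, while the list's camera adjusted p was 0.469. These members too were picked by the authors on arrays of this series, but for this comparison with an HSC array among the alphaKO arrays, as given below. Irs2 and Insr were higher in HSC than in LMPP, by 1.39 and 0.48, so that array may have favoured their choice. In LMPP deltaKO and DKO 6 of the 8 passed adjusted over the list alone, with list means of -0.26 and -0.09. Sesn1 had values of 1.44 and 1.39 there against the same WT arrays, so its difference from WT is not particular to p110α loss. In alphaKO Rictor had a value of 0.84. Without LMPP WT replicate 2 the values were 0.45 for Rictor, 0.62 for Sesn1, 0.62 for Insr and 1.41 for Irs2. The 9 myeloid genes had a mean of 0.05. The authors' deposited table for LMPP alphaKO listed 299 clusters, and its alphaKO averages equalled those of LMPP alphaKO replicates 1 and 2 with HSC alphaKO replicate 2 for 100% of them, within log2 0.006. With the 3 arrays labelled LMPP alphaKO, 14.0% of the averages in the authors' deposited table were matched. On component 1 HSC alphaKO replicate 2 lay with the HSC arrays, at -38.9, and LMPP alphaKO replicate 3 with the LMPP arrays, at 79.6. Without LMPP WT replicate 2 limma made 1 call, and without LMPP WT replicate 1, which left that array alone, it made 4454.

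In LMPP deltaKO 10 named genes differed from WT, 9 of them lower. Wfdc21, a gene of neutrophil secretions, fell from log2 15.57 ± 1.19 (SD, n = 2) in WT to 8.95 ± 0.84 (SD, n = 3) in deltaKO, and Trem1, a receptor gene of neutrophils and monocytes, fell from 11.33 ± 0.02 to 6.77 ± 0.36. The heavy chain genes Ighv1-5, Ighv1-73, Ighv1-62-1 and Ighv1-79 fell by 5.80, 3.26, 3.12 and 1.54. Plaur, the urokinase receptor gene, Il1r2, the decoy interleukin-1 receptor gene, and the chemokine gene Cxcl16 fell by 1.94, 1.84 and 1.84. Prepl, a peptidase gene, rose by 1.01. Adjusted p by limma was 0.0397 for Wfdc21, 0.0340 for Ighv1-5, 0.0257 for Il1r2 and 0.0214 for each of the other 7 genes. With identical clusters counted once Ighv1-62-1, Ighv1-73, Ighv1-79 and Trem1 kept their call and the other 6 genes lost theirs, with adjusted p from 0.0911 for Plaur, Cxcl16 and Prepl to 0.158 for Wfdc21. None of the 10 passed with array weights, with only the 2 groups in the fit or without any 1 of the deltaKO replicates. In LMPP alphaKO, which keeps p110δ, Prepl had a value of 0.97 against the same WT arrays. Ighv1-5, Ighv1-73, Ighv1-62-1, Ighv1-79 and Cxcl16 had values of -3.92, -2.05, -2.88, -1.26 and -0.89 there. For these genes the difference from WT cannot be assigned to p110δ loss alone. Trem1, Plaur and Il1r2 were not lower in alphaKO, at 11.50, 11.57 and 9.20. The 14 granulocyte genes, Wfdc21 among them, averaged -0.06 in alphaKO against WT.

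All 9 myeloid genes had negative values, with a mean of -4.24, a camera adjusted p of 3.17e-09 and a fry adjusted p of 0.0434, against an adjusted p of 0.132 with an estimated correlation. Of them 6 passed adjusted over the list alone and 0 over all clusters, and, as with the lists below, their choice by the authors on these arrays leaves no independent evidence of direction. Lactoferrin (Ltf) was at 7.45 ± 1.65 in deltaKO and 15.33 ± 1.82 in WT, and the calprotectin gene S100a9 was at 10.15 ± 1.69 against 17.33 ± 0.03. The macrophage gene Vcam1 had a value of -2.36 and the mast cell gene Hdc one of -2.22. The quiescence and immediate early genes had a mean of -1.60 in 3 of 3 members (camera adjusted p 0.00133, and adjusted p 0.132 with an estimated correlation), with 3 past the threshold adjusted over the list alone and 0 over all clusters. NF-kB genes had a mean of -0.71 (camera adjusted p 0.0335, and adjusted p 0.132 with an estimated correlation). With only named genes as the background none of these 3 lists was called. The camera adjusted p was then 0.0556 for myeloid, 0.588 for quiescence and immediate early and 0.743 for NF-kB genes. The handling stress genes Ddit3 and Gadd45b had values of -1.59 and -1.60. Over the alternatives these ranged from -2.21 to -0.97 and from -2.15 to -1.05, as the 2 WT arrays differed, with Ddit3 at 10.35 and 11.59. All 4 p53 targets and all 3 adhesion genes passed adjusted over the list alone and 0 over all clusters, in mixed directions. Of the p53 targets 3 were lower and Sesn1 was higher, at 1.44. Of the adhesion genes 2 were lower, with the leukocyte integrin gene Itgb2 at -2.02, and Tek was higher, at 0.97. Camera called neither list, with an adjusted p of 0.0889 for p53 targets and 0.209 for adhesion genes.

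The calls numbered 128, of which 17 rose and 111 fell, with 4028 clusters at an unadjusted p below 0.05. The excess of falls was not shared by the unadjusted criterion with 1.5-fold, which gave 2269 higher and 1077 lower, or by the authors' deposited table, with 426 higher and 336 lower, and it was smaller with all 23 arrays in 1 fit, at 183 and 238. The 128 calls held 37 distinct sets of values, because 96 of the falling calls shared all values with another call. The largest such set, of 63 unnamed clusters, fell from 8.83 ± 0.80 in WT to 6.40 ± 0.29 in deltaKO. Counted once, identical clusters gave 6 calls, and the count was 5 with each array centred on its median, 0 with array weights, 0 with only the 2 groups in the fit, 421 with all 23 arrays in 1 fit and 177 with quantile normalization. It was 158 without LMPP WT replicate 2, 5008 without LMPP WT replicate 1, and 0 without any 1 of the deltaKO replicates. The authors' deposited table listed 762 clusters, with Ltf at a fold of -260.55, and its smallest FDR p-value was 0.779.

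**Figure D3:**
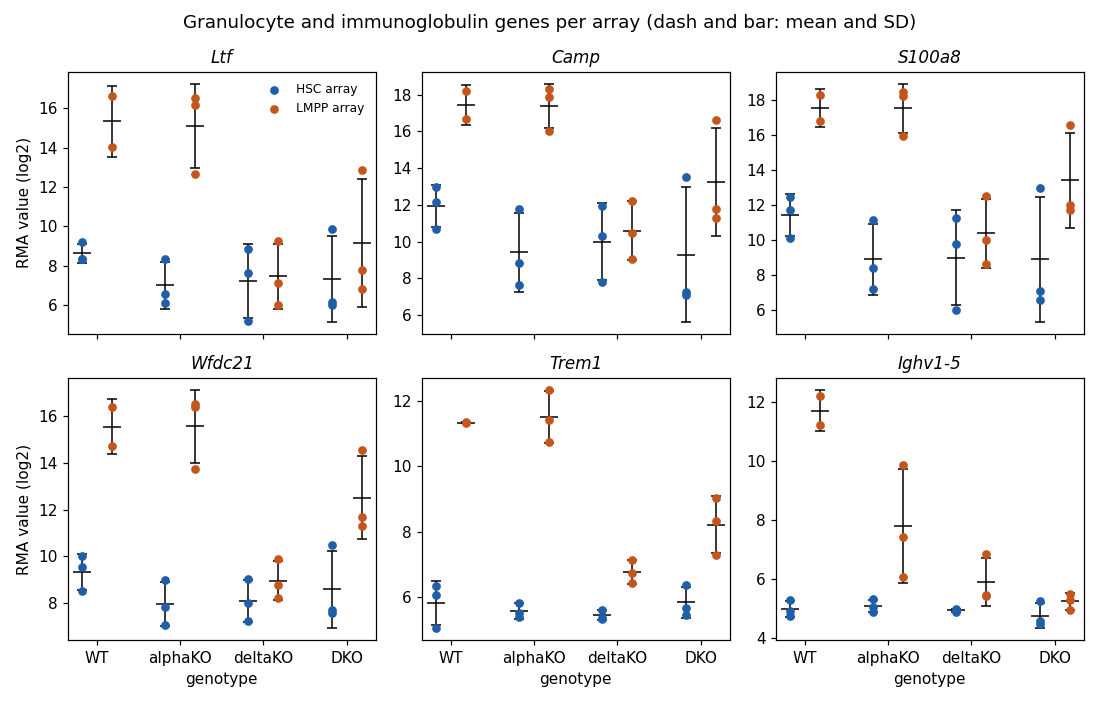
RMA values (log2) of 5 granulocyte genes and Ighv1-5 by genotype, with 1 point per array, HSC in blue and LMPP in orange, and dash and bar for the mean and SD of a group (2 arrays in LMPP WT and 3 in the others). Trem1 in LMPP averaged 11.33 in WT, 11.50 in alphaKO, 6.77 in deltaKO and 8.22 in DKO.

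In LMPP without both isoforms Ighv1-12, Trem1 and Nr4a1 had means below WT and Gimap4 a mean above it. Ighv1-12 measured log2 10.38 ± 0.41 (SD, n = 3) in DKO and 16.94 ± 2.10 (SD, n = 2) in WT. Trem1 was at 8.22 ± 0.88 against 11.33 ± 0.02, and Nr4a1 was at 14.41 ± 0.07 against 16.39 ± 0.03. Gimap4, a GTPase gene of lymphocytes, was at 7.64 ± 0.37 against 5.75 ± 0.10. Limma adjusted p was 0.157 for Ighv1-12, 0.176 for Trem1, 0.296 for Nr4a1 and 0.231 for Gimap4.

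Limma made 0 calls, with 4673 clusters at an unadjusted p below 0.05 and a smallest adjusted p of 0.0502, held by Ighv1-73 and Ighv1-79. The quiescence and immediate early genes had a mean of -1.98 in 3 of 3 members (camera adjusted p 0.000757 and fry adjusted p 0.0188, against an adjusted p of 0.153 with an estimated correlation), with 3 past the threshold adjusted over the list alone and 0 over all clusters. NF-kB genes had a mean of -0.86 (camera adjusted p 0.0321, and adjusted p 0.153 with an estimated correlation). Of 9 myeloid genes 6 had negative values, with a mean of -2.20 (camera adjusted p 0.0105, and adjusted p 0.375 with an estimated correlation). With only named genes as the background the camera adjusted p was 0.281 for quiescence and immediate early genes and 0.424 for both NF-kB and myeloid genes. The authors picked the members of all these lists on these arrays, so the counts are not independent evidence. Handling stress genes again had negative values, with Ddit3 at -1.68, from -2.30 to -1.07 over the alternatives. The HSC identity genes Selp and Tek had values of 1.43 each and passed adjusted over the list alone, with 0 over all clusters and a camera adjusted p of 0.0629. Srm and Cdc6 had values of 1.05 and 1.03, and Sqstm1 a value of -1.01, from -1.37 to -0.65 over the alternatives. The authors' deposited table listed 410 clusters, with Ighv1-5 at a fold of -86.61. The count of 0 became 2 without LMPP WT replicate 2, 5472 without LMPP WT replicate 1 and 102 with all 23 arrays in 1 fit.

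A comparison of DKO with alphaKO, which uses no WT array, tested loss of p110δ on the p110α-deficient background. In LMPP Plaur fell from log2 11.57 ± 0.08 (SD, n = 3) to 9.06 ± 0.41 (SD, n = 3), and Il1r2 fell from 9.20 ± 0.31 to 6.63 ± 0.46. Limma's adjusted p was 0.0248 for both, the 2 calls of this comparison. Nr4a1 had a value of -2.13 (adjusted p 0.547) and the matricellular protein gene Thbs1 one of -2.73 (adjusted p 0.154). In HSC Nr4a1 had a value of -1.63 (adjusted p 0.406) and Pim2 one of 1.56 (adjusted p 0.122).

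In LMPP DKO against alphaKO the quiescence and immediate early genes had a mean of -1.68 in 3 of 3 members, with a camera adjusted p of 1.05e-05 and an adjusted p of 0.0402 with an estimated correlation. NF-kB genes had a mean of -0.95 in 4 of 4 members and an adjusted p of 0.0402 with an estimated correlation. The HSC identity genes had a mean of 0.66 in 3 of 3 members and an adjusted p of 0.0418 with an estimated correlation. Of 8 FOXO targets 7 had negative values, with a mean of -0.53 and an adjusted p of 0.0402 with an estimated correlation. With only named genes as the background the camera adjusted p of these 4 lists was 0.132, 0.326, 0.132 and 0.552, and their members were picked by the authors on these arrays. Camera also called myeloid genes, with a mean of -2.25, p53 targets, with a mean of -0.85, and adhesion genes, with a mean of -0.68, and their adjusted p was 0.115, 0.0848 and 0.109 with an estimated correlation. Cdkn1a, at -1.66, is a member of the quiescence, FOXO and p53 lists. The handling stress genes Ddit3 and Gadd45b had a mean of -0.88 in LMPP. The group of 10 immediate early genes, which holds both, averaged 12.37 in LMPP alphaKO replicate 1 against 11.40 and 11.11 in replicates 2 and 3. In HSC DKO against alphaKO 4 clusters were called, among them TC0400001906.mm.1, which rose, and the immediate early genes had a mean of -1.46 (camera adjusted p 0.000190, and adjusted p 0.203 with an estimated correlation). The group of 10, which holds these genes, averaged 12.34 in HSC alphaKO replicate 1 against 11.27 and 11.33 in replicates 2 and 3. The 2 calls in LMPP became 0 without DKO replicate 1 or any 1 of the alphaKO replicates, without DKO replicate 3 the only call was a cluster that rose, so that Plaur and Il1r2 lost theirs there too, and the 4 in HSC became 0 without DKO replicate 2 or 3 or any 1 of the alphaKO replicates.

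Loss of p110α on the p110δ-deficient background was tested as DKO against deltaKO. In LMPP the granulocyte genes Wfdc21, at 3.57, and Trem3, at 3.27, had positive values, as did Gimap4, at 1.56. In HSC Pim2 had a value of 1.52 and Ncam2 one of 1.94. Limma made 0 calls in either cell type, with adjusted p of 0.918 for Wfdc21, 0.935 for Trem3 and 0.675 for Gimap4 in LMPP and 1 for both HSC genes, and with 1221 clusters in LMPP and 1011 in HSC at an unadjusted p below 0.05. In LMPP all 9 myeloid genes were positive, with a mean of 2.04 (camera adjusted p 5.36e-08, and adjusted p 0.177 with an estimated correlation). LMPP DKO replicate 2 stood apart, with Camp at 16.62 against 11.78 and 11.30 in the other DKO arrays and 9.02 to 12.23 in the deltaKO arrays.

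The interaction contrast asked whether the DKO value differed from the sum of the single knockouts on the log2 scale. In HSC Pim2 measured 8.64 in WT, 8.61 in alphaKO, 8.65 in deltaKO and 10.17 in DKO, an interaction of 1.56 (SE 0.39), and Ndrg2 had an interaction of 1.21 (SE 0.39). In LMPP Ighv1-62-1 was at 9.69 in WT, 6.81 in alphaKO, 6.57 in deltaKO and 6.34 in DKO, an interaction of 2.65 (SE 0.50). The single knockout values of -2.88 and -3.12 add up to a level below background, so a positive interaction of this gene is not evidence of a joint effect. Limma made 0 calls in either cell type, with 676 clusters in HSC and 1762 in LMPP at an unadjusted p below 0.05. Adjusted p was 1.000 for Pim2 and 0.860 for Ighv1-62-1.

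The effect of a knockout differed between cell types for 4 genes by limma's F test over the 3 knockouts. These were Ighv1-79, Ighv1-62-1, Ighv1-73 and Trem1, with adjusted p of 0.00241, 0.00547, 0.00513 and 0.00547. In deltaKO against WT the value of Trem1 was -0.38 in HSC and -4.57 in LMPP, and that of Ighv1-62-1 was 0.12 and -3.12. In HSC WT they averaged 5.82 and 5.43, Ighv1-73 5.33 and Ighv1-79 4.80, near the background 95th percentiles of the HSC arrays, 4.88 to 5.30, so a decrease there could hardly be seen. Without LMPP WT replicate 2 the count was 9, and without LMPP WT replicate 1 it was 2790. It was 49 without LMPP alphaKO replicate 1, 8 without LMPP alphaKO replicate 3, 8 without LMPP DKO replicate 2 and 7 without LMPP deltaKO replicate 2.

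Calls shared between knockouts of 1 cell type numbered 1 cluster, TC0400001906.mm.1 on chromosome 4, higher in HSC deltaKO and DKO. At an unadjusted p below 0.05 and 1.5-fold, HSC deltaKO and DKO shared 626 clusters that were higher and 127 that were lower, against 84.5 and 80.9 in simulated unchanged groups sharing WT arrays and 44.1 and 3.83 for independent lists. The covariance of their log2 fold changes was 0.0962 against a simulated 0.0467. For HSC alphaKO the covariance was 0.0419 with deltaKO and 0.0464 with DKO, against 0.0465 and 0.0466 simulated. In LMPP it was 0.266 for deltaKO and DKO, 0.185 for alphaKO and deltaKO and 0.187 for alphaKO and DKO, against 0.0925, 0.0926 and 0.0927. The WT arrays could not be split into groups of 2, and part of the excess may come from shared controls. The simulated arrays were independent normal draws with 1 spread per cluster, so none stood apart as LMPP WT replicate 2 does. The simulated values therefore cannot decide how much of the LMPP excess comes from that array. Without shared arrays, the effects of p110δ loss on the 2 backgrounds correlated across clusters, which are not independent replicates, at 0.476 in HSC and 0.362 in LMPP. Of 100 groupings of the arrays 2 in HSC and 1 in LMPP were as high as the real one, itself included, so that 1 regrouping exceeded it in HSC. The highest other value in LMPP was 0.346. The same correlation for p110α loss was 0.0677 and 0.0142, with 0.402 and 0.313 as the highest among other regroupings.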

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

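The tests on granulocyte and immediate early genes and on p110α loss below were chosen after the results were seen, as were the comparisons of DKO with the single knockouts. The other chromosome 4 tests were prompted by clusters of that chromosome seen among the largest changes, and their limits, like those of the splits, were written before the counts were made.

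The difference between cell types in the effect of a knockout was tested by limma, and 4 genes differed for deltaKO and 5 clusters for DKO. For deltaKO the effect in HSC minus that in LMPP was 1.60 for Ighv1-79, 3.25 for Ighv1-62-1, 3.28 for Ighv1-73 and 4.19 for Trem1. For DKO it was 1.91 for Ighv1-79, 6.23 for Ighv1-5, 3.37 for Ighv1-62-1, 3.76 for Ighv1-73 and 1.46 for the unnamed cluster TC0600003143.mm.1. In HSC the named genes lay near background in all genotypes, with Ighv1-5 at 4.77 in DKO, so their differences are not evidence that HSC respond less, while TC0600003143.mm.1 had values of 0.69 in HSC and -0.78 in LMPP. In the authors' deposited table for LMPP alphaKO, 14.0% of the knockout averages equalled those of the arrays labelled LMPP alphaKO, a signal from a source outside the tests of the report.

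The 14 granulocyte genes in LMPP averaged -5.27 in deltaKO, -3.43 in DKO and -0.06 in alphaKO against WT, and in DKO against alphaKO they averaged -3.38 with only 2 of 14 lower in every array. In HSC the same genes averaged -0.94 in deltaKO, -0.87 in DKO and -1.04 in alphaKO against WT, so the fall there did not follow p110δ loss. The LMPP WT arrays alone, 1 of which stands apart, do not account for the LMPP pattern. Against the alphaKO arrays the genes still averaged -5.22, with 14 of 14 lower in every deltaKO than in every alphaKO array. Such genes vary together, with an estimated correlation of 0.63 for the LMPP myeloid list. The 14 therefore count as 1 separation of 3 arrays from 3, which chance gives 10% of the time in 1 direction or the other. Unsorted marrow in the WT and alphaKO sorts stays open, as immunoglobulin genes differed between alphaKO and WT by -1.65 relative to granulocyte genes, between the limits set for the test. Mature granulocytes in those sorts may also account for the pattern, and the early myeloid genes Ctsg and Ms4a3 did not decide it, averaging -1.96 in deltaKO against alphaKO with overlapping arrays, and 0.93 in DKO against WT, where the granulocyte genes were low. A change of the progenitors themselves on loss of p110δ is the biological alternative and cannot be told apart from these, as the sort gates would remove mature granulocytes but all 14 genes were picked by the authors on these arrays.

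The 10 immediate early genes averaged -1.20 in HSC deltaKO, -1.29 in HSC DKO, -1.31 in LMPP deltaKO and -1.57 in LMPP DKO against WT, and -0.38 and -0.36 in alphaKO of HSC and LMPP. A handling response in the WT arrays alone was tested without them: DKO minus alphaKO averaged -1.22 in LMPP and -0.91 in HSC, the latter short of the -1 set to exclude it. The genes averaged 12.34 in HSC alphaKO replicate 1 against 11.27 and 11.33 in replicates 2 and 3, and 12.37 against 11.40 and 11.11 in LMPP. Both differences would be smaller without alphaKO replicate 1. Without HSC WT replicate 2 the HSC mean over deltaKO and DKO was -0.86 in place of -1.25, also short of that limit. Handling that differed between arrays with and without p110δ could not be tested, since 0 named members of the handling list lay outside the 10 genes, and it cannot be told apart from an effect of p110δ loss, the biological alternative. In WT, alphaKO and DKO, though not in deltaKO, the highest array of both cell types had the same place in the order of deposition, and as the labels do not say whether these share pools, the -1.22 and -0.91 may not be independent.

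Loss of p110δ moved 50 clusters in 1 direction at an unadjusted p below 0.05 in all 4 contrasts (deltaKO against WT and DKO against alphaKO in both cell types, which may share pools), and loss of p110α moved 0. Of the 50, 12 lay on chromosome 4, which holds Pik3cd, 3.57 times the share among clusters tested (Fisher's exact p 8.98e-05, too small where clusters share sequence). This ratio met the limit set for an interval of chromosome 4 carried along with the targeted Pik3cd allele, a candidate explanation for the excess. The limit against a response spread evenly over the genome was set on the same ratio, so the 24.0% on that chromosome is not separate evidence. Chromosome 4 was chosen after its clusters were seen among the largest changes. The 12 hold TC0400001906.mm.1 and the predicted genes Gm13051, Gm13247 and Gm13150, which have consecutive identifiers. The count therefore does not decide between the 2 explanations. An uneven number of chromosome 4 clusters in any such contrast was left undecided, with 0 clusters for p110α loss. The interval would not account for the 38 clusters elsewhere, Nr4a1 and Ptgs2 among them, nor is Klf4 near Pik3cd, at position -896 among coding genes counted from Pik3cd in the reference, while Dhrs3 is at -60.

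Splits of the arrays were counted for each comparison of groups of 3. With 10 splits of 6 arrays no share under 0.05 can be reached. HSC deltaKO against WT gave 3 calls, HSC DKO against WT 3, HSC DKO against alphaKO 4 and LMPP DKO against alphaKO 2, each with 0 calls as the highest of the other splits and 1 split as large, the real one. HSC alphaKO against WT gave 0 calls and 0 in the others, HSC DKO against deltaKO 0 with 107 as the highest other, and LMPP DKO against deltaKO 0 with 1. With a real count of 0 all 10 splits are as large whatever the data, so these 3 counts test nothing. For HSC against LMPP 1 of 100 splits, the real one, gave as many as 7694 calls, the highest other giving 1018. As the populations were sorted by opposite gates, a large difference was built into the design, and this count is only a check of the labels. For the interaction in HSC the real count was 0, so all 100 splits are as large by construction and nothing is tested. The highest other split gave 317 calls, and whether clusters that vary together would give as many was not tested.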

How the results depend on the processing

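Counting identical clusters once, restricting the list background to named genes, and comparing DKO with the single knockouts were alternatives chosen after the results were seen. No paired analysis was possible because the labels give no number that pairs arrays between groups, and the order of deposition names no pair. Counts below are of calls by limma unless stated, and the cause of each change was not tested.

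For HSC alphaKO against WT the count stayed at 0 in every alternative except an unadjusted p below 0.05 with 1.5-fold, which gave 359. For HSC deltaKO against WT the 3 calls became 1 with quantile normalization, 5 with the trend and robust prior, 0 with sex as a covariate, 0 with only the 2 groups compared and 1670 by the unadjusted criterion. Leaving out 1 array gave between 0 (without HSC deltaKO replicate 1) and 3 (without HSC WT replicate 1). For HSC DKO against WT the 3 calls became 1 with the filter at the 75th percentile, 5 with the trend and robust prior, 5 with array weights, 5 with all 23 arrays in 1 fit, 1 with only the 2 groups and 1462 by the unadjusted criterion. Leaving out 1 array gave between 0 (without HSC WT replicate 3) and 5 (without HSC DKO replicate 1). With quantile normalization 50.0% of its calls were higher in DKO, against 33.3% before.

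For LMPP alphaKO against WT the count of 0 became 4 without a filter, 1 with the filter at the 75th percentile, 5 with all 23 arrays and 2124 by the unadjusted criterion, and stayed at 0 with the arrays of the deposited table, an alternative also chosen after the results were seen. Leaving out 1 array gave between 0 (without LMPP alphaKO replicate 1) and 4454 (without LMPP WT replicate 1). For LMPP deltaKO against WT the 128 calls became 5 with centred arrays, 0 with array weights, 421 with all 23 arrays, 0 with only the 2 groups, 3346 by the unadjusted criterion and 6 with identical clusters counted once. Leaving out 1 array gave between 0 (without LMPP deltaKO replicate 1) and 5008 (without LMPP WT replicate 1). For LMPP DKO against WT the count of 0 became 8 without a filter, 3 with centred arrays, 102 with all 23 arrays, 3709 by the unadjusted criterion and 2 with identical clusters counted once. Leaving out 1 array gave between 0 (without LMPP DKO replicate 1) and 5472 (without LMPP WT replicate 1). Without LMPP WT replicate 1 the lone WT array is assumed to vary like the other groups.

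The interaction in HSC gave 484 by the unadjusted criterion and 0 without any 1 array. In LMPP it gave 1671 by the unadjusted criterion, and between 0 (without LMPP DKO replicate 1) and 1393 (without LMPP WT replicate 1). For HSC against LMPP the 7694 calls became 4646 with the filter at the 75th percentile, 4262 by the unadjusted criterion and 2789 with WT arrays only, with 7870 when genotype and sex were a block, and between 6708 (without HSC deltaKO replicate 2) and 9944 (without LMPP WT replicate 1) when 1 array was left out. With centred arrays 64.1% of its calls were higher in HSC, against 54.9% before. The 4 genes whose knockout effect differed between cell types became 8 without a filter, 1 with the filter at the 75th percentile, 8 with array weights and 2103 by the unadjusted criterion, and between 4 (without HSC DKO replicate 1) and 2790 (without LMPP WT replicate 1) when 1 array was left out.

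For HSC DKO against alphaKO the 4 calls became 2 with quantile normalization and 0 with sex as a covariate, and between 0 (without HSC alphaKO replicate 1) and 6 (without HSC DKO replicate 1) when 1 array was left out. For LMPP DKO against alphaKO the 2 calls became 1 with sex as a covariate, and between 0 (without LMPP DKO replicate 1) and 1 (without LMPP DKO replicate 2), while without LMPP DKO replicate 3 both were lost and 1 other cluster was called, higher in DKO. DKO against deltaKO stayed at 0 in both cell types without any 1 array. Camera made 15 list calls over 6 comparisons, 0 with an estimated correlation and 4 with named genes as the background. Those 4 were G2 and M phase and myeloid genes in HSC alphaKO, and quiescence and immediate early genes in HSC deltaKO and DKO. Fry made 5 calls, among them HSC identity in LMPP DKO, which camera had not called. Wdr5b in LMPP alphaKO had a value of 0.56, which reversed to -0.089 without LMPP alphaKO replicate 1 and was 1.34 without replicate 3. In LMPP deltaKO against WT 600 of 709 values of named genes were unchanged in label, 73 weaker and 36 stronger.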

Other observations

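The values in this part were chosen after the results were seen and no further test was made. Dhrs3, a gene of retinol metabolism, had log2 differences of 0.91 in HSC deltaKO against WT, 0.92 in HSC DKO against alphaKO, 1.15 in LMPP deltaKO against WT and 1.41 in LMPP DKO against alphaKO. The SE of its HSC differences was 0.40. Rbm44, an RNA-binding protein gene, had values of 0.78, 0.78, 1.37 and 0.88 in the same order of contrasts. Of the 50 clusters with 1 direction in these 4 contrasts, 43 were higher and 7 lower without p110δ. The early myeloid genes Ctsg and Ms4a3 averaged 0.93 in LMPP DKO against WT and 2.48 against deltaKO, and were higher in every DKO than in every deltaKO array.

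Ighv1-5 was at log2 9.87, 7.44 and 6.07 in LMPP alphaKO replicates 1, 2 and 3 and at 11.21 and 12.21 in LMPP WT replicates 1 and 2. By the limits read from the authors' deposited tables, the arrays labelled LMPP alphaKO gave 245 clusters against WT, 126 of them among the 299 of the authors' deposited table. The arrays whose averages equal those of the authors' deposited table gave 302 clusters, with all 299 among them.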
